A study of Mus musculus with 32 samples.

How the data were processed

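RNA was measured in sorted marrow HSPCs, of wild-type donor origin per the labels, from 16 biological replicates, 4 in each of 4 groups. The labels list 2 technical replicates for each biological replicate, but there is 1 table per biological replicate, and whether reads of the technical replicates were merged is not given in the sources used here. Lineage-positive cells were depleted with magnetic beads before fluorescence-activated sorting, per the labels. Also per the labels, RNA was extracted with a column kit for small samples, while the library kit named is a droplet kit for single cells. The tables hold 1 value per gene and replicate, so they were treated as bulk RNA-seq, and the kit stays unresolved. Groups and replicate numbers were taken from the sample titles. The labels do not say that replicates are separate mice, so p-values measure the spread between these samples. Chromatin accessibility data named in the labels were not analysed here.

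Reads were trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.10a and quantified with RSEM 1.3.1 on the mouse genome GRCm38, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here. The deposited tables give, per gene, RSEM expected counts, which are estimates that need not be whole, and TPM, which are scaled for gene length and sum to the same total in each library, per the file headers. RSEM divides reads that map to several genes in proportion to its estimates. Values of near-identical families, such as Csf2rb and Csf2rb2, the Oas, Ifit and Ly6 genes, Mt1 and Mt2, Clca3a1 and the H2 genes, are therefore uncertain, as are those of overlapping antisense genes. Gene symbols and coordinates came from GENCODE's GRCm38 annotation, which matched 45143 of the 45706 gene identifiers.

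Expected counts were rounded to whole numbers. Genes were kept by edgeR's expression filter by group, which left 15186 genes holding 99.928% of the counts. Libraries were scaled by the trimmed mean of M values (TMM), and edgeR 4.0.16 (R 4.3.3) fitted 1 mean per group to all 16 libraries by quasi-likelihood. The common biological coefficient of variation was 0.306 with 12 residual degrees of freedom. The contrasts were LPS against PBS in naive and in experienced mice, experienced against naive after PBS, after LPS and averaged over both, and the interaction, the LPS response of experienced minus that of naive mice. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. The median SE of a log2 difference was 0.25 in each contrast of 4 against 4 libraries, 0.35 in the interaction and 0.17 in the averaged contrast. CPM, counts scaled to the library size, were computed with TMM-scaled library sizes.

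The test was checked on simulated counts with the means and sizes of these libraries, in which 200 genes were changed, 50 per fold. Of genes changed 2-fold it recovered 38% between experienced and naive PBS (14968 genes in the step), 54% between experienced and naive LPS (14963), 48% and 64% for LPS in naive (14969) and experienced mice (14985), 10% for the interaction (14947) and 66% for the averaged contrast (14954). At 4-fold the shares were 76%, 80%, 66%, 72%, 62% and 96%, and at 1.5-fold 2%, 8%, 4%, 14%, 4% and 16%. At most 11 unchanged genes were called in any of these.

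In all, 40 gene lists covering pathways, blood lineages, other cells a sort can hold and signs of handling were fixed, and the 39 with at least 5 tested members were compared with other genes by limma's camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera called 17 lists for LPS in naive mice, 18 in experienced mice, 13 between experienced and naive PBS, 14 between experienced and naive LPS, 16 for the interaction and 14 for the averaged contrast. With a correlation estimated from the data it called 0 in all 6 contrasts, and fry, which asks whether a list moves one way on balance, called 17, 15, 0, 0, 0 and 0. Each list was also scored per library as the mean log2 CPM of its members, each gene centred on its mean over the libraries, and compared by a two-sided exact permutation test over the 70 arrangements of 4 against 4 libraries. No list, 0 of 39, passed that test after adjustment in the 4 contrasts between groups. The smallest p this permutation test can give is 0.0286, so a few lists at that value cannot pass after adjustment over 39. The count of 0 thus decides nothing about the calls of the other tools, up to 18.

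Named genes were chosen by rule. In each contrast these were the 8 called genes with the largest rise and the 8 with the largest fall among those with a mean log2 CPM of at least 2 and groups that do not overlap, leaving out gene models, receptor segments of lymphocytes, Xist and Y-linked genes. To these were added up to 4 members with the lowest adjusted p of each list described and 21 genes fixed by name. Some of these genes are not reported here. Groups of 4 do not overlap by chance in 2.86% of genes. The share was 29.2% and 17.3% for LPS in naive and experienced mice, 4.04% between experienced and naive PBS and 1.62% between experienced and naive LPS. Of the 21 genes, 10 passed for LPS in naive mice, 9 in experienced mice and 0 in the other 4 contrasts by edgeR's test. The design, the tests, the lists, the rule for named genes and all alternatives but 4 were set before the data were examined. Which of the fixed lists to describe was chosen after their values were seen.

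Alternatives were other scalings (relative log expression and upper quartile), no filter and a stricter filter (50 counts in 4 libraries), an adjusted p of 0.01, the replicate number as a block, fits of only the libraries compared, leaving out mitochondrial, haemoglobin, immunoglobulin and ribosomal protein genes, limma voom with quality weights, limma on log2(TPM + 1), DESeq2 1.42.0 and leaving out each library in turn. The 4 added after seeing the data left out the 2 or the 4 libraries with the lowest correlation with their own group, left out naive LPS replicate 3 with experienced LPS replicate 4, or used the log2 mitochondrial share as a covariate. The correlation of the difference at rest with the LPS response was set beside 20 simulations of unchanged groups and beside the 6 splits of the naive PBS libraries. None of the 24 pairs of libraries within a group differed by less than the sampling noise. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15), and random draws used the seed 20261127.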

Results

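RNA sequencing measured expression in haematopoietic stem and progenitor cells (HSPCs), the marrow cells that renew the blood lineages, from mice whose leukaemia had regressed and from controls. The HSPCs came from wild-type donor marrow that carried both CD45 alleles and were sorted as lineage-negative, Kit-positive and Sca1-positive cells. In experienced mice, 800000 wild-type marrow cells had been transplanted into irradiated recipients beside 200000 cells able to express the human leukaemia fusion MLL-AF9 under doxycycline. In naive mice the partner cells carried only the doxycycline-responsive activator. Doxycycline started 6 to 8 weeks after transplantation, lasted 5 weeks and was then withdrawn for 4 weeks. The mice next received phosphate-buffered saline (PBS) or lipopolysaccharide (LPS), a bacterial product sensed by Toll-like receptor 4, and were sacrificed 24 h later. The design asks whether normal HSPCs that had lived beside a leukaemia differ at rest, and whether they answer an inflammatory challenge differently.

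The 4 groups (naive PBS, experienced PBS, naive LPS and experienced LPS) held 4 biological replicates each, and each replicate had 1 table, so n = 4 per group. The labels do not say whether a replicate was 1 mouse or a pool. Libraries held 7.72 M to 22.3 M expected counts (M, mega), with group means of 19.5 ± 2.40 M (SD, n = 4) in naive PBS, 15.4 ± 3.50 M in experienced PBS, 15.3 ± 6.29 M in naive LPS and 14.8 ± 7.47 M in experienced LPS. The first principal component, 35.8% of the variance, separated the 8 LPS from the 8 PBS libraries. The second, 17.3%, did not separate naive from experienced mice. Experienced LPS replicate 4 was the least typical library, with a mean correlation of 0.915 with its own group, the fewest detected genes (14887) and 7.30% of its counts from mitochondrial genes, against 1.91% to 2.50% in the other 3 libraries of that group. The next least typical were naive LPS replicate 2 (correlation 0.936), experienced PBS replicate 4 (0.947, with 5.94% mitochondrial counts) and experienced PBS replicate 3 (0.950).

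**Figure D1:**
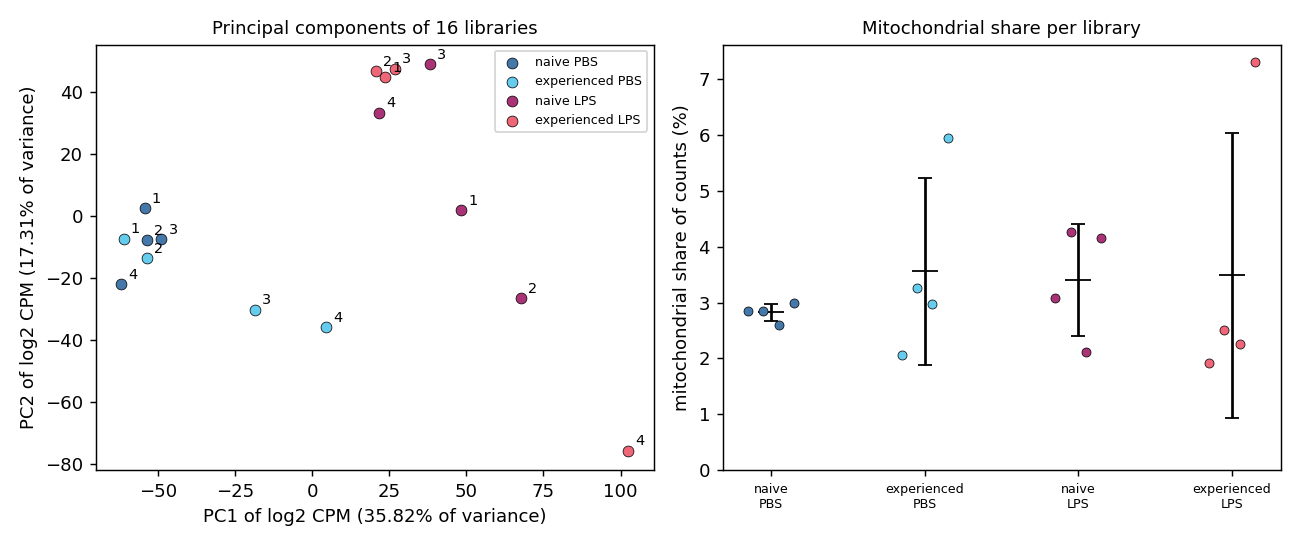
Left, the first and second principal components of log2 CPM for the 16 libraries, with the share of variance on each axis and 1 point per library coloured by group. Right, the mitochondrial share of each library's counts in percent, with the group mean ± SD (n = 4). The 8 LPS libraries lie to the right of the 8 PBS libraries, and experienced LPS replicate 4 has the highest share, 7.30%.

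In naive mice, HSPCs sorted after LPS had lower levels of many lymphoid and stem cell transcripts. Transcripts of the interferon response and of basophil, mast cell and erythroid development were higher. Dntt, the DNA polymerase that diversifies lymphocyte receptors (ENSMUSG00000025014, chromosome 19, 41029275 to 41059525, GRCm38), fell from 176 ± 35.6 to 4.75 ± 1.52 CPM (counts scaled to library size, mean ± SD, n = 4), a log2 change of −5.25 (SE 0.45). Flt3, the cytokine receptor of early lymphoid-primed progenitors (ENSMUSG00000042817, chromosome 5, 147330741 to 147400489), fell from 275 ± 22.1 to 40.4 ± 5.23 CPM. Csf2rb2, a signalling subunit of the interleukin-3 receptor (ENSMUSG00000071714, chromosome 15, 78282507 to 78305721), rose from 12 ± 4.37 to 170 ± 61.1 CPM, and Gzmb, a protease of cytotoxic and mast cell granules, from 0.953 ± 0.664 to 39.5 ± 26.0 CPM. Irf7, a transcription factor that amplifies interferon production (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), rose from 21.8 ± 5.89 to 109 ± 38.2 CPM. Of 15186 genes tested, 1490 were higher and 1803 lower after LPS by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and 487 and 1094 of these differed by more than 2-fold.

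Lymphoid and stem cell genes made up the clearest losses in naive mice. Of 19 lymphoid-primed genes, 14 fell and 0 rose, and 18 fell when adjusted over the list alone. Besides Dntt (adjusted p = 4.91e-06, edgeR) and Flt3 (log2 change −2.77, SE 0.32), they included Lsp1, a leukocyte cytoskeletal protein (−2.04, SE 0.17), and Satb1, a chromatin organiser of lymphoid cells (−1.96, SE 0.25). The list was lower than other genes by camera (adjusted p = 3.82e-16, and adjusted p = 0.0622 with an estimated correlation). Of 11 B and plasma cell genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone), among them Ighm (−3.52, SE 0.53), Jchain (−3.72, SE 0.70) and the B-cell linker Blnk (−3.03, SE 0.59). Their camera result was an adjusted p = 7.49e-05, and adjusted p = 0.183 with an estimated correlation. Ighm is also transcribed in uncommitted progenitors. Of 24 stem cell identity genes, 13 fell and 4 rose, the same numbers when adjusted over the list alone (camera, adjusted p = 0.000658, and adjusted p = 0.341 with an estimated correlation). Mecom, a transcription factor needed for stem cell maintenance (ENSMUSG00000027684, chromosome 3, 29951296 to 30548008), fell from 81.7 ± 9.74 to 20.1 ± 5.64 CPM. Hlf (−2.40, SE 0.27), Ltb (−2.63, SE 0.39) and Procr, the endothelial protein C receptor that marks stem cells (−2.14, SE 0.34), fell as well. Clca3a1, a member of a family of near-identical surface proteins whose reads can be shared, went the other way (3.38, SE 0.32).

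Genes that hold stem cells in quiescence and genes of the MLL-AF9 programme were lower after LPS in naive mice too. Of 18 quiescence genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with falls of Foxo3 (−0.62, SE 0.15), Tob1 (−0.76, SE 0.17) and the cyclin-dependent kinase inhibitor Cdkn1c (−1.87, SE 0.50). By camera the list had an adjusted p = 0.00482, and adjusted p = 0.183 with an estimated correlation. Of 24 genes linked to MLL-AF9 leukaemia, 11 fell and 3 rose, and these numbers were unchanged when adjusted over the list alone (camera, adjusted p = 0.00482, and adjusted p = 0.341 with an estimated correlation). The falls included Hoxa9 (−0.63, SE 0.15), Hoxa5 (−1.27, SE 0.27), Eya1 (−1.12, SE 0.21) and Meis1 (−0.68, SE 0.20), developmental transcription regulators that are also active in normal HSPCs. Myc, the growth-promoting transcription factor counted in the same list, rose (0.55, SE 0.15). Of 10 major histocompatibility complex (MHC) class II genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone), with H2-Ob at −1.53 (SE 0.23), H2-DMa at −0.84 (SE 0.20) and the class II transactivator Ciita at −1.18 (SE 0.33). Their camera adjusted p = 0.00685, and adjusted p = 0.461 with an estimated correlation.

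The gains in naive mice were led by interferon-induced genes and by the machinery of ribosome production. Of 33 interferon-induced genes, 24 rose and 0 fell (29 and 0 adjusted over the list alone), among them Ifitm3, a membrane protein that blocks virus entry (1.72, SE 0.24), the nucleic acid sensor Zbp1 (2.35, SE 0.36) and the deconjugating enzyme Usp18 (1.65, SE 0.26). By camera the list had an adjusted p = 1.79e-15, and adjusted p = 0.183 with an estimated correlation. Of 22 ribosome biogenesis genes, 19 rose and 0 fell (22 and 0 adjusted over the list alone), including Rrp12 (0.91, SE 0.15), Nop56 (0.77, SE 0.14), Nop2 (0.94, SE 0.18) and Utp20 (0.74, SE 0.14). Their camera adjusted p = 4.69e-12, and adjusted p = 0.183 with an estimated correlation. Of 12 heat shock genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), such as the chaperones Hsph1 (1.48, SE 0.22), Hspd1 (1.32, SE 0.30) and Hspa8 (0.86, SE 0.15), with a camera adjusted p = 4.51e-06, and adjusted p = 0.183 with an estimated correlation. Of 17 unfolded protein response genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone). The chaperones Hspa5 (0.97, SE 0.24), Hyou1 (0.92, SE 0.19) and Calr (1.24, SE 0.30) rose, and Trib3, a pseudokinase induced by stress, fell (−2.89, SE 0.63). That list's camera adjusted p = 0.00694, and adjusted p = 0.37 with an estimated correlation. Ccl5, a chemokine, rose by 3.97 (SE 0.55) and Lcn2, an iron-sequestering protein of innate defence, by 4.88 (SE 0.69).

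Basophil, mast cell and erythroid transcripts were higher in the same naive LPS libraries. Of 15 basophil, mast cell and eosinophil genes, 11 rose and 1 fell (11 and 2 adjusted over the list alone), with Ms4a2 and Fcer1a, subunits of the high-affinity receptor for immunoglobulin E, at 4.40 (SE 0.59) and 3.0 (SE 0.31), the interleukin-33 receptor Il1rl1 at 3.97 (SE 0.65) and Lmo4 at 1.33 (SE 0.22). Their camera adjusted p = 1.61e-07, and adjusted p = 0.209 with an estimated correlation. Of 20 erythroid genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone), including the transferrin receptor Tfrc (2.28, SE 0.29), the erythroid factors Gata1 (2.25, SE 0.48) and Klf1 (2.92, SE 0.76) and the water channel Aqp1 (2.66, SE 0.68). That list had a camera adjusted p = 7.49e-05, and adjusted p = 0.461 with an estimated correlation. Among the genes with the largest changes, Mt1 and Mt2, metal-binding metallothioneins, rose by 3.85 (SE 0.75) and 3.84 (SE 0.96), and Robo4, an endothelial and stem cell guidance receptor (−3.57, SE 0.26), Scube3 (−4.02, SE 0.37), Paqr5 (−3.48, SE 0.33), Kcng1 (−3.93, SE 0.51), Emp1 (−3.54, SE 0.53) and Apob (−3.83, SE 0.66) fell. Of the genes that define the sort, Ly6a, which encodes Sca1, rose from 37.7 ± 11.9 to 124 ± 41.5 CPM, while Kit was at 735 ± 44.5 and 547 ± 132 CPM and did not pass (edgeR adjusted p = 0.0671). Sca1 is part of the sort, so a changed mix of sorted cells and changed levels within cells cannot be told apart here. Mpo, a granule enzyme of myeloid progenitors, and Mki67, a proliferation marker, did not pass either (0.43, SE 0.40, and 0.64, SE 0.28).

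All 12 of these lists lost their camera call with an estimated correlation and kept it with fry, a rotation test of whether a list moves one way. Calls of Meis1, Ciita and Myc ended without 1 of the naive libraries: Meis1 without naive PBS replicate 4 or naive LPS replicate 1 or 3 (−0.59, −0.64 and −0.52), Ciita without naive PBS replicate 1 or 2 (−1.07 and −1.13) and Myc without naive PBS replicate 2 (0.49). Calls of Eya1, Utp20, Hspa8, Calr, Hspa5 and Myc also ended with limma on log2(TPM + 1). Of the calls 45.3% were higher, against 19.9% with limma on log2(TPM + 1) and 35.0% with upper-quartile factors, and the higher genes numbered 768, 938 and 902 without naive PBS replicates 2, 3 and 4.

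**Figure D2:**
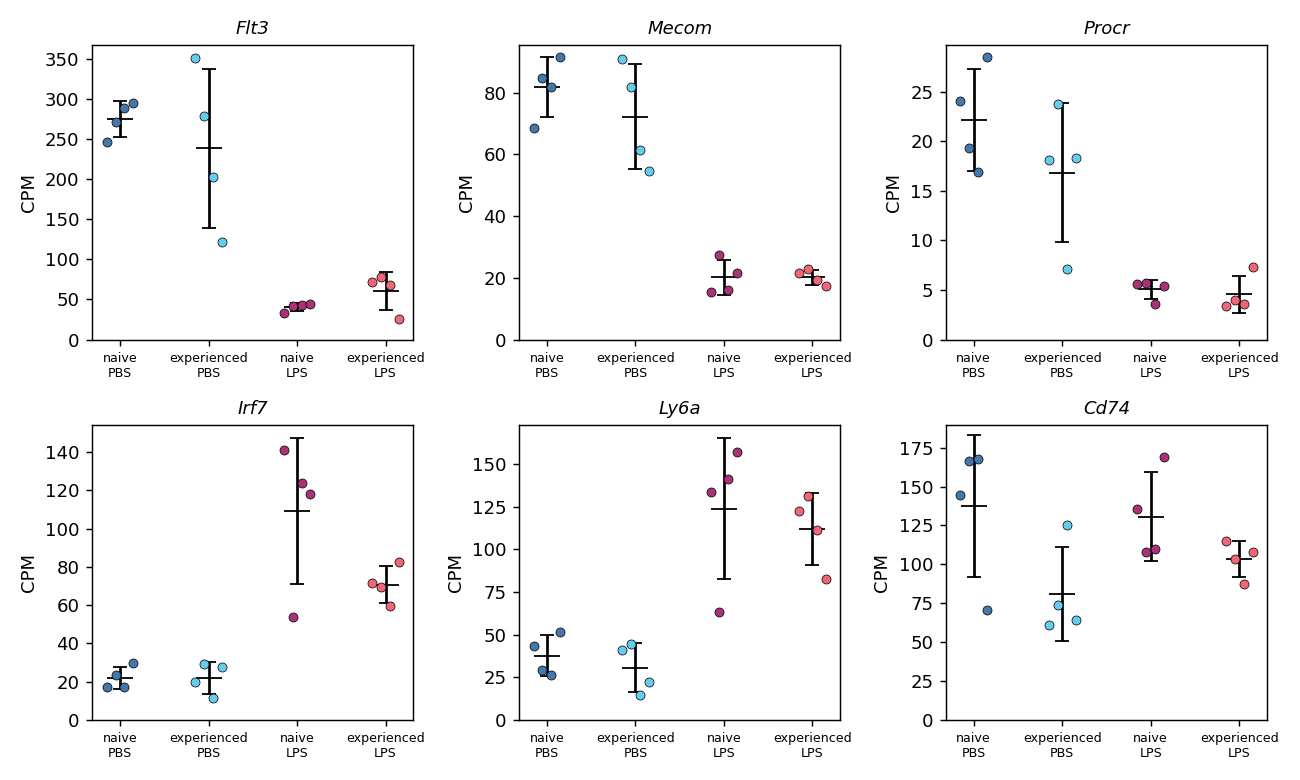
CPM of Flt3, Mecom, Procr, Irf7, Ly6a and Cd74 in each of the 16 libraries, by group, with the group mean ± SD (n = 4). Flt3, Mecom and Procr are lower and Irf7 and Ly6a higher in both LPS groups than in the PBS groups, and Cd74 is at 137 ± 45.7 CPM in naive PBS and 80.9 ± 30.0 CPM in experienced PBS.

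In experienced mice, lymphoid and quiescence transcripts were lower after LPS, and inflammatory, ribosome production, basophil and megakaryocyte transcripts were higher. As in naive mice, these can be changes within cells or in the mix of sorted cells. Dntt fell from 155 ± 86.2 to 9.68 ± 3.36 CPM (log2 change −3.97, SE 0.42) and Flt3 from 239 ± 99.1 to 60.5 ± 23.8 CPM. Csf2rb2 rose from 11.8 ± 4.33 to 144 ± 23 CPM, Ccl5 from 1.26 ± 1.03 to 30.0 ± 11.5 CPM and Cxcl10, a chemokine induced by interferon, from 1.59 ± 0.762 to 15.3 ± 3.86 CPM. In all, 686 genes were higher and 1254 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 199 and 757 of them by more than 2-fold.

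Of 19 lymphoid-primed genes, 11 fell and 0 rose in experienced mice (15 and 0 adjusted over the list alone), led by Lsp1 (−2.22, SE 0.17), Dntt, Ighm (−3.89, SE 0.54) and Satb1 (−1.71, SE 0.25). The camera adjusted p = 1.07e-13, and adjusted p = 0.118 with an estimated correlation. Of 11 B and plasma cell genes, 4 fell and 0 rose (6 and 0 adjusted over the list alone), which were Ighm, Jchain (−4.01, SE 0.70), Blnk (−3.33, SE 0.60) and Igkc (−2.89, SE 0.66), with a camera adjusted p = 3.80e-05, and adjusted p = 0.118 with an estimated correlation. Of 18 quiescence genes, 4 fell and 0 rose, the same when adjusted over the list alone, among them Txnip, an inhibitor of thioredoxin (−1.32, SE 0.22), Foxo3 (−0.68, SE 0.15) and Cdkn1c (−1.94, SE 0.51). Their camera adjusted p = 0.00313, and adjusted p = 0.209 with an estimated correlation. Of 24 MLL-AF9 programme genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone), including Mecom (−1.84, SE 0.20), Hoxa9 (−0.98, SE 0.15) and Eya1 (−1.19, SE 0.21). That list's camera adjusted p = 0.000363, and adjusted p = 0.283 with an estimated correlation. Of 24 stem cell identity genes, 8 fell and 4 rose (10 and 6 adjusted over the list alone), and the list did not pass by camera (median −0.49, adjusted p = 0.0727). Of single stem cell genes, Hlf (−2.11, SE 0.26), Ltb (−2.55, SE 0.39) and Procr (−1.91, SE 0.34) fell and Clca3a1 rose (2.72, SE 0.31).

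Of 33 interferon-induced genes, 7 rose and 0 fell in experienced mice (10 and 0 adjusted over the list alone), with Ifitm3 at 1.88 (SE 0.24), the virus-tethering protein Bst2 at 1.62 (SE 0.27), Irf7 at 1.69 (SE 0.30) and Usp18 at 1.41 (SE 0.26). Their camera adjusted p = 3.82e-07, and adjusted p = 0.376 with an estimated correlation. Of 25 genes of the nuclear factor κB and tumour necrosis factor response, 6 rose and 1 fell (9 and 4 adjusted over the list alone), with Ccl5 (4.51, SE 0.58), Ccl2 (2.22, SE 0.42) and the feedback inhibitors Tnfaip3 (2.15, SE 0.41) and Nfkbia (1.01, SE 0.24) among the rises. That list's camera adjusted p = 0.0177, and adjusted p = 0.495 with an estimated correlation. Of 14 genes of the interleukin-6, granulocyte colony-stimulating factor and Stat3 response, 3 rose and 1 fell (5 and 1 adjusted over the list alone). The acute phase proteins Saa3 (5.88, SE 0.89), Lcn2 (3.84, SE 0.66) and Lrg1 (4.24, SE 0.75) rose and Csf3r, the granulocyte colony-stimulating factor receptor, fell (−0.89, SE 0.24). The camera adjusted p = 0.00383, and adjusted p = 0.453 with an estimated correlation. Both inflammatory scores were higher after LPS in naive mice too. The interleukin-6 score was −0.28 ± 0.19 in naive PBS and 0.305 ± 0.13 in naive LPS (mean ± SD, n = 4), and −0.47 ± 0.26 and 0.45 ± 0.53 in experienced mice. The nuclear factor κB score was −0.09 ± 0.03 and 0.17 ± 0.29 in naive mice, and −0.28 ± 0.11 and 0.20 ± 0.38 in experienced mice. Of 22 ribosome biogenesis genes, 17 rose and 0 fell (21 and 0 adjusted over the list alone), such as Rrp12 (1.02, SE 0.15), Nop16 (0.82, SE 0.16) and Mybbp1a (0.78, SE 0.15), with a camera adjusted p = 1.07e-13, and adjusted p = 0.16 with an estimated correlation. Of 12 heat shock genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone), Hspa8 among them (0.62, SE 0.15), with a camera adjusted p = 0.000335, and adjusted p = 0.283 with an estimated correlation. Of 17 unfolded protein response genes, 6 rose and 0 fell (8 and 0 adjusted over the list alone), including Hyou1 (1.09, SE 0.19), Sdf2l1 (1.73, SE 0.38) and Hspa5 (0.99, SE 0.24). Their camera adjusted p = 0.000167, and adjusted p = 0.277 with an estimated correlation.

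Of 15 basophil, mast cell and eosinophil genes, 7 rose and 1 fell in experienced mice (9 and 2 adjusted over the list alone). Fcer1a (2.88, SE 0.32), Ms4a2 (3.07, SE 0.56) and Gzmb (3.27, SE 0.61) rose and the chemokine Ccl9 fell (−1.20, SE 0.18). The camera adjusted p = 0.000363, and adjusted p = 0.376 with an estimated correlation. Of 19 megakaryocyte genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone), with the platelet integrin chains Itgb3 (2.17, SE 0.24) and Itga2b (1.82, SE 0.25) and the platelet glycoproteins Gp1bb (2.01, SE 0.28) and Gp5 (1.05, SE 0.17). That list's camera adjusted p = 1.04e-07, and adjusted p = 0.118 with an estimated correlation. Its score was −0.14 ± 0.13 in naive PBS and 0.10 ± 0.27 in naive LPS, and −0.39 ± 0.19 and 0.43 ± 0.22 in experienced mice. Other large changes were rises of Cntnap1 (3.17, SE 0.26) and Kcnj5 (3.29, SE 0.59) and falls of Robo4 (−3.05, SE 0.25), Tle2 (−2.99, SE 0.31), Paqr5 (−3.12, SE 0.33), Bpifc (−2.93, SE 0.42), Sytl1 (−3.14, SE 0.57) and Apob (−3.19, SE 0.65). Ly6a rose (1.87, SE 0.34), as did Tfrc (1.68, SE 0.29) and the cell cycle inhibitor Cdkn1a (0.99, SE 0.27). Ptprc, which encodes CD45, fell (−0.52, SE 0.14), and Kit (−0.44, SE 0.16, edgeR adjusted p = 0.0835) and Mpo (0.37, SE 0.40) did not pass. The gene model CT010467.1 passed by a narrow margin (3.30, SE 1.05, edgeR adjusted p = 0.0493) with 105 CPM in experienced LPS replicate 3 and 5.44 to 13.3 CPM in the other 3.

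In experienced mice too, all 12 of these lists that camera called lost their call with an estimated correlation, and the nuclear factor κB and interleukin-6 lists had no call with fry either, the former also none without experienced PBS replicate 3. The counts depended on single libraries, with 1456 genes higher and 1701 lower without experienced LPS replicate 4, 302 higher and 763 lower without experienced PBS replicate 1, 321 and 787 without experienced PBS replicate 2, 328 and 828 without experienced LPS replicate 1, 361 and 869 without replicate 2 of that group, 393 and 712 without replicate 3 and 1085 and 1403 without naive LPS replicate 2. Leaving out 1 experienced library ended the calls of Cdkn1c (−1.79 without PBS replicate 2, −1.57 without LPS replicate 3), Csf3r (−0.75 and −0.82 without PBS replicates 1 and 2), Hspa8 (0.54 and 0.59 without the same 2), Cdkn1a (0.81 without PBS replicate 3, 0.93 to 0.95 without LPS replicate 1, 2 or 3) and Ptprc (−0.43 to −0.54 without any of PBS or LPS replicates 1 to 3), and that of CT010467.1 (1.32 without LPS replicate 3). Eya1, Nop16, Nfkbia, Sdf2l1, Hspa5, Hspa8 and Cdkn1a had no call with limma on log2(TPM + 1), and Igkc, Csf3r and Cdkn1a none when only the libraries compared were fitted. Of the calls 35.4% were higher, against 15.7% with limma on log2(TPM + 1), a scale on which the median of all genes lay at −0.13.

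The responses of naive and experienced mice ran in parallel across genes. Of the genes that rose in naive mice, 446 also rose in experienced mice, where 67.3 would be expected of independent lists, and of those that fell 942 also fell, against 149 expected. No gene, 0 of them, was called in opposite directions. Fold changes correlated with Pearson's r = 0.70 and Spearman's rho = 0.67 across 15186 genes, which are not independent replicates, and the slope of experienced on naive was 0.61. Noise in the naive changes lowers such a slope, so it does not show a weaker response in experienced mice. The r was 0.52 without naive LPS replicate 3 and experienced LPS replicate 4, a pair chosen because each resembled the other group, so that leaving it out parts the responses by construction.

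The interaction asks directly whether the LPS response differed, and no single gene passed it. Cdkn1a, the cell cycle inhibitor p21, was 20.7 ± 2.26 CPM in naive PBS and 21.2 ± 4.76 CPM in naive LPS, against 15.9 ± 6.57 and 31.7 ± 7.95 CPM in experienced mice, a difference of 0.96 on the log2 scale (SE 0.37). Pf4, a platelet chemokine, had a difference of 1.64 (SE 0.54). The interferon-induced Cmpk2 (−1.0, SE 0.31), Xaf1 (−0.94, SE 0.33) and Oas2 (−1.32, SE 0.47), the erythroid Klf1 (−2.63, SE 1.02) and Car1 (−3.29, SE 1.27) and the basophil genes Gzmb (−2.11, SE 0.84) and Il1rl1 (−2.05, SE 0.83) had negative differences. Car1 was at 334 ± 455 CPM in experienced mice after PBS and 332 ± 260 CPM after LPS, against 50.4 ± 26.9 and 491 ± 226 CPM in naive mice. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower at an adjusted p of 0.05, with 695 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.884. DESeq2 called 1 gene higher and both limma fits 0.

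As groups, the 33 interferon-induced genes had a median difference of −0.54 (camera, adjusted p = 4.08e-07, and adjusted p = 0.567 with an estimated correlation) and the 19 megakaryocyte genes of 0.43 (camera, adjusted p = 4.78e-06, and adjusted p = 0.567 with an estimated correlation). The 20 erythroid genes had −1.81 (camera, adjusted p = 5.22e-06, and adjusted p = 0.567 with an estimated correlation) and the 15 basophil genes −1.0 (camera, adjusted p = 0.000154, and adjusted p = 0.567 with an estimated correlation). In each of the 4 lists 0 members passed over all genes and 0 when adjusted over the list alone. Erythroid and basophil transcripts were high in experienced PBS replicates 3 and 4, and without the 4 least typical libraries the basophil list had a mean of 0.36 and no call. Without naive LPS replicate 3 and experienced LPS replicate 4 together, the megakaryocyte list had no call (mean 0.37).

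**Figure D3:**
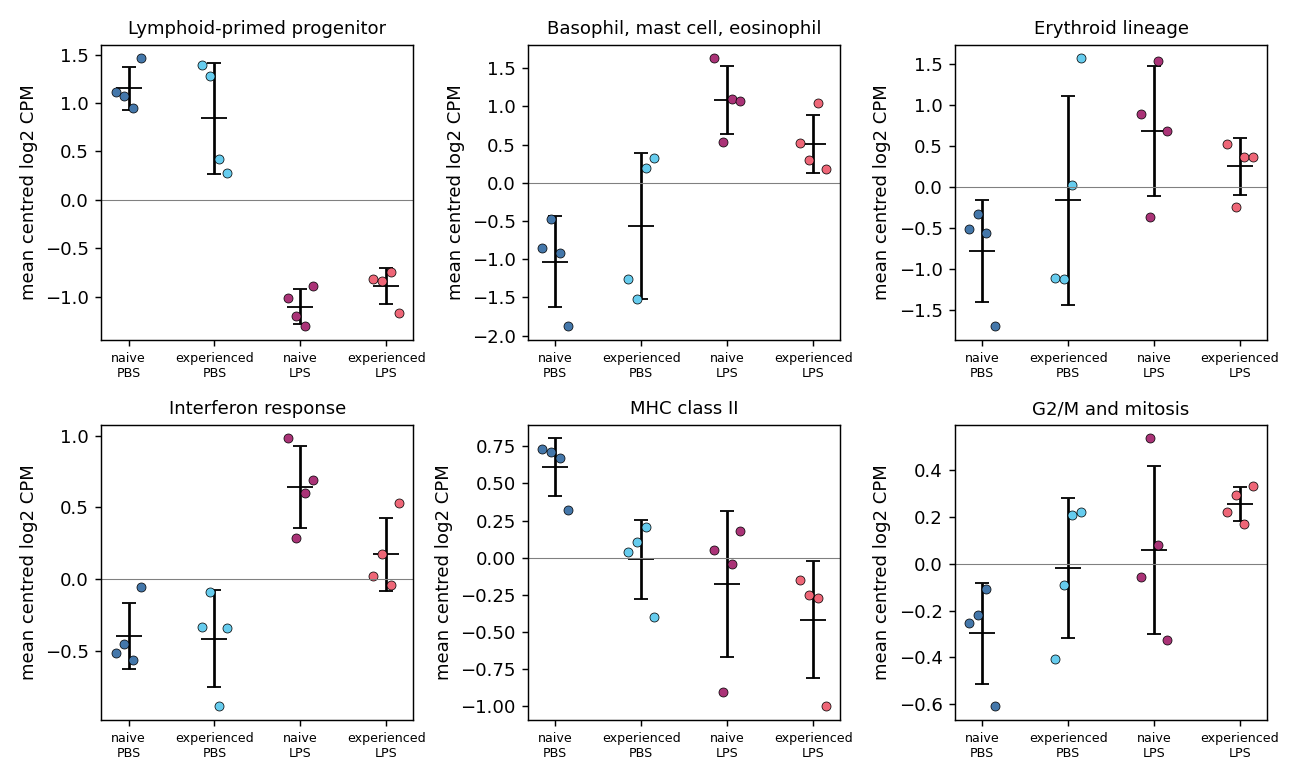
Score of 6 gene lists in each of the 16 libraries (mean log2 CPM over the list's members, each gene centred on its mean over all libraries), by group, with the group mean ± SD (n = 4). The interferon score is 0.64 ± 0.29 in naive LPS and 0.17 ± 0.26 in experienced LPS, and the MHC class II score 0.61 ± 0.20 in naive PBS and −0.01 ± 0.27 in experienced PBS.

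At rest, after PBS, MHC class II genes had lower mean levels in HSPCs of experienced than of naive mice. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a chain of the molecule that presents antigen to helper T cells, was at 85.7 ± 17.6 CPM in naive and 51.6 ± 9.28 CPM in experienced mice (log2 difference −0.73, SE 0.17). H2-Aa was at 61.7 ± 12.5 and 30.7 ± 11.7 CPM, H2-Eb1 at 32.2 ± 7.13 and 19.1 ± 7.96 CPM, and Ciita at 12.1 ± 3.01 and 6.01 ± 0.858 CPM. Cd74, the invariant chain that accompanies class II molecules, was at 137 ± 45.7 and 80.9 ± 30.0 CPM (−0.76, SE 0.26). None of these genes passed over all genes by edgeR's test, while 5 of the 10 class II genes were lower and 0 higher when adjusted over the list alone. The list had a median of −0.71 (camera, adjusted p = 7.10e-11, and adjusted p = 0.228 with an estimated correlation), and all 4 experienced libraries scored below all 4 naive ones (exact permutation p = 0.0286, the smallest that 70 arrangements give, 0.223 after Benjamini-Hochberg adjustment over 39 lists). Class II was not alone in this. Scores of LPS sensing by Toll-like receptors, the nuclear factor κB response, macrophages and dendritic cells, and glycolysis separated the same way. The LPS-sensing score was 0.24 ± 0.06 in naive and 0.03 ± 0.11 in experienced PBS.

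Other lists passed at rest by camera with the preset correlation but not by fry, with 0 members passing over all genes and 0 when adjusted over the list alone in each. The 30 genes of mitosis were higher (median 0.35, camera, adjusted p = 1.25e-08, and adjusted p = 0.494 with an estimated correlation), with Hmmr at 0.71 (SE 0.31) and the mitotic kinase Plk1 at 0.50 (SE 0.22). Their score was −0.41 and −0.09 in experienced PBS replicates 1 and 2 and 0.21 and 0.22 in replicates 3 and 4, against −0.30 ± 0.22 in naive PBS. The 18 macrophage and dendritic cell genes were lower (median −0.59, camera, adjusted p = 0.00566, and adjusted p = 0.46 with an estimated correlation), with the haem-degrading enzyme Hmox1 at −1.53 (SE 0.51). Stem cell identity genes, 24 in number, were lower (median −0.28, camera, adjusted p = 0.000437, and adjusted p = 0.494 with an estimated correlation). Their score was 0.21 and 0.57 in experienced PBS replicates 1 and 2 and −0.09 and 0.05 in replicates 3 and 4, against 0.51 ± 0.25 in naive PBS. The 20 erythroid genes (median 1.22, camera, adjusted p = 4.77e-06, and adjusted p = 0.494 with an estimated correlation) and the 15 basophil genes (median 0.62, camera, adjusted p = 0.0155, and adjusted p = 0.62 with an estimated correlation) were higher by list, but their spread was wide. Car1, an erythroid carbonic anhydrase, was at 50.4 ± 26.9 CPM in naive and 334 ± 455 CPM in experienced mice, and Il1rl1 at 7.90 ± 2.90 and 25.4 ± 26.8 CPM. Tfrc was at 77.6 ± 10.5 and 137 ± 68.8 CPM, and Mpo at 1172 ± 395 and 1613 ± 963 CPM.

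By edgeR's quasi-likelihood test 0 genes were higher and 0 lower between experienced and naive PBS at an adjusted p of 0.05, with 451 at an unadjusted p under 0.05 and a smallest adjusted p of 0.988. DESeq2 called 2 genes higher, limma voom with quality weights 2 lower (H2-Ab1 and H2-Aa) and limma on log2(TPM + 1) 1 lower. The direction of Car1, Il1rl1 and Mpo and of the erythroid and basophil lists rested on experienced PBS replicates 3 and 4. Without the 4 least typical libraries these genes were at −0.95, −0.56 and −0.35 and the lists had means of −0.50 and −0.93, while the class II list kept its call (mean −0.56).

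After LPS, interferon-induced genes had lower mean levels in HSPCs of experienced than of naive mice, but no single gene of the list passed by edgeR's test. Oas3, a sensor of double-stranded RNA (ENSMUSG00000032661, chromosome 5, 120753098 to 120777661), was at 97.5 ± 23.1 CPM in naive and 59.0 ± 10.8 CPM in experienced mice (log2 difference −0.73, SE 0.22), and Oas2, a close paralogue, at 131 ± 50.6 and 69.7 ± 26.9 CPM. Zbp1 was at 45.9 ± 23 and 24.1 ± 9.35 CPM, Ifit1 at 28.4 ± 7.30 and 16.5 ± 7.50 CPM and Irf7 at 109 ± 38.2 and 70.7 ± 9.58 CPM. The 33 interferon-induced genes had a median difference of −0.49 (camera, adjusted p = 1.43e-16, and adjusted p = 0.424 with an estimated correlation), and the list score differed by −0.47 (exact permutation p = 0.0571, 0.743 after Benjamini-Hochberg adjustment). Experienced LPS replicate 4 scored 0.53, among the naive LPS libraries (0.29 to 0.98).

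The 22 interferon-γ-induced genes, GTPases and others, were lower as well (median −0.41, camera, adjusted p = 7.07e-06, and adjusted p = 0.424 with an estimated correlation), with the GTPase Irgm1 at −0.46 (SE 0.18), although Irf8, a myeloid transcription factor in the list, was at 0.98 (SE 0.35). The 30 mitosis genes were higher (median 0.15, camera, adjusted p = 1.23e-05, and adjusted p = 0.734 with an estimated correlation), with Ccnb1 at 0.54 (SE 0.19) and Plk1 at 0.47 (SE 0.22). The 19 megakaryocyte genes were higher (median 0.16, camera, adjusted p = 5.18e-05, and adjusted p = 0.424 with an estimated correlation), with Pf4 at 1.05 (SE 0.39) and Vwf, the platelet adhesion protein, at 0.46 (SE 0.21). The 15 basophil genes were lower (median −0.44, camera, adjusted p = 0.000444, and adjusted p = 0.669 with an estimated correlation), with Fcer1a at −0.55 (SE 0.29). The 10 MHC class II genes were lower by a smaller median than at rest (−0.24, camera, adjusted p = 0.0418, and adjusted p = 0.745 with an estimated correlation), and their list score differed by −0.24 (exact permutation p = 0.457, not passing). In each of these 6 lists 0 members passed over all genes and 0 when adjusted over the list alone. Flt3 was at 0.59 (SE 0.30) and Cdkn1a at 0.58 (SE 0.27).

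By edgeR's quasi-likelihood test 0 genes were higher and 0 lower between experienced and naive LPS, with 491 at an unadjusted p under 0.05 and a smallest adjusted p of 0.9999. DESeq2 called 2 genes higher and limma voom with quality weights 2 lower. The LPS libraries did not group by their labels. Naive LPS replicate 3 had a mean correlation of 0.979 with experienced LPS replicates 1 to 3 and of 0.958 with its own group, and experienced LPS replicate 4 of 0.932 with naive LPS replicates 1, 2 and 4 and of 0.915 with its own. Naive LPS replicates 1 and 4 also correlated more with experienced LPS replicates 1 to 3 (0.963 and 0.966) than with their own group (0.960 and 0.953). Without the 2 least typical libraries, both from LPS groups, 0 genes were higher and 0 lower. Without experienced PBS replicates 3 and 4 as well, which are not compared here but enter the gene filter and the shared estimate of spread, 70 were higher and 153 lower, with Oas3 at −0.91, Oas2 at −1.34, Zbp1 at −1.52, Ifit1 at −1.24 and Irf7 at −0.94 then passing. Without naive LPS replicate 3 and experienced LPS replicate 4 the megakaryocyte list (mean 0.15) and the basophil list (mean −0.56) had no call. The mitosis list had none without naive LPS replicate 4, the megakaryocyte list none without experienced LPS replicate 4 and the basophil list none without naive LPS replicate 1. The class II list had none without naive LPS replicate 1, 3 or 4 (means −0.17, −0.21 and −0.12), experienced LPS replicate 3 or 4 (−0.28 and −0.11) or naive LPS replicate 3 and experienced LPS replicate 4 together (−0.094).

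Averaged over PBS and LPS, the same libraries with 8 a side, MHC class II genes had lower and mitosis genes higher mean levels in experienced mice. H2-Ab1 differed by −0.59 (SE 0.12), Ciita by −0.75 (SE 0.24) and Cd74 by −0.55 (SE 0.18). Of the 10 class II genes, 5 were lower by edgeR's test when adjusted over the list alone and 0 over all genes (median −0.42, camera, adjusted p = 6.10e-13, and adjusted p = 0.0772 with an estimated correlation). Plk1 differed by 0.48 (SE 0.16), the mitotic kinase Aurka by 0.31 (SE 0.11) and Ccnb1 by 0.36 (SE 0.14). The 30 mitosis genes had a median of 0.22 (camera, adjusted p = 7.03e-17, and adjusted p = 0.272 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. At rest the high mitosis scores of experienced mice were those of PBS replicates 3 and 4 (0.21 and 0.22), against −0.41 and −0.09 in replicates 1 and 2. By edgeR's quasi-likelihood test 0 genes were higher and 0 lower, with 294 at an unadjusted p under 0.05 and a smallest adjusted p of 1. DESeq2 called 0 and limma voom with quality weights 2 lower, H2-Ab1 among them.

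Across genes, the difference between experienced and naive mice at rest correlated with the naive response to LPS, in part because both share controls. The log2 differences correlated with Pearson's r = 0.50 and Spearman's rho = 0.54, but both comparisons share the naive PBS libraries. Simulated groups, both unchanged from those libraries, gave a mean r of 0.49. That r cannot be set against the measured one, since LPS changed many genes and the simulation changed none. The covariance was 0.18 against 0.08 simulated, a difference of 0.10. With the naive PBS libraries split so that each comparison used its own pair, r was 0.32 on average (0.26 to 0.39 over the 6 splits). In these splits the comparisons share no library, so shared controls do not raise r. Erythroid and basophil genes, higher in naive mice after LPS, were also those that experienced PBS replicates 3 and 4 held at high levels. On the first principal component, replicates 1 and 2 of that group lay at −61.3 and −53.8, among the naive PBS libraries (−62.1 to −49.0). Replicates 3 and 4 lay at −18.7 and 4.29, between the naive PBS and the LPS libraries (20.6 to 102.5). These data do not show that the correlation is a trait of all 4 experienced PBS libraries.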

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

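The tests of the 3 patterns weighed below were chosen after the results were seen, as were the fits without the 4 least typical libraries and with the mitochondrial share as a covariate; the counts of splits in the other fits were planned. Of 596 groups of 4 values, 56 (9.4%) held 1 library far from the other 3, where 5.07% of 100000 simulated groups of 4 did so by chance. Of the 56, 26 lay in experienced LPS replicate 4 and 6 in naive PBS replicate 4.

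No gene, 0 of them, passed between experienced and naive LPS by edgeR's test (491 at an unadjusted p under 0.05, 2 by DESeq2 and 2 by limma voom), a count that 35 of 35 splits of the 8 libraries reach by construction, so it decides nothing about chance. The split that exchanges naive LPS replicate 3 with experienced LPS replicate 4 called 2097 genes, which points to a structure of the samples other than their labels. A technical axis may underlie it, since the mitochondrial share parted the 2 sides of that split by 0.575 percentage points. The spread of the 4 least typical libraries may hide differences, since 223 genes passed without them, although 0 did without the 2 from LPS groups alone. The count thus depends on leaving out experienced PBS replicates 3 and 4, which are not compared. They enter the gene filter (15480 genes without the 2 libraries, 15840 without the 4) as well as the shared spread, and these were not told apart. Exchanged labels stay open, since the interferon score of naive LPS replicate 3 (0.60) lay within those of the other naive LPS libraries (0.29 to 0.98) and above those of experienced LPS replicates 1 to 3 (−0.04 to 0.18), but that of experienced LPS replicate 4 (0.53) lay among the naive ones, and the score of 1 library excludes nothing. An effect of past leukaemia stays open and untested beside these, and for the structure itself no biological explanation was tested.

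Erythroid and basophil transcripts were high in 2 experienced PBS libraries, replicates 3 and 4, with erythroid scores of 0.025 and 1.57 against −1.69 to −0.33 in the other 6 PBS libraries and basophil scores of 0.20 and 0.32 against −1.88 to −0.47. More committed progenitors in the sorted cells are a candidate explanation. In both, 4 of 5 lineage lists lay beyond the other 6 libraries, but the erythroid and basophil lists are the pattern itself and add no support. The granulocyte-monocyte list lay above (0.45 and 0.45 against −0.80 to 0.11) and the lymphoid-primed list below (0.42 and 0.28 against 0.95 to 1.46), while the megakaryocyte list did not lie beyond. RNA quality cannot be told apart from it, since 1 of the 2 libraries had a mitochondrial share above the other 6 and 2 libraries are too few to part these. Past leukaemia of these mice stays open as well and was not tested separately.

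MHC class II transcripts were lower by list in experienced PBS, and the 2 atypical experienced libraries were not the whole source, since the list's mean was −0.56 without the 4 least typical libraries. Fewer B cells, which the lineage-negative gate would remove, stay open, since the B and plasma cell genes went both ways around a median of 0.045, with Cd79b at 19.0 ± 2.17 and 16.8 ± 3.41 CPM in naive and experienced PBS, Igkc at 126 ± 42.4 and 184 ± 148 CPM and Ighm, which uncommitted progenitors also transcribe, at 220 ± 90.0 and 377 ± 255 CPM. Fewer dendritic cells and macrophages, which that gate would remove too, could also lower class II transcripts, and the look at their single genes and the bound set for the B cell genes were added after their values were seen. Their list score differed by −0.48, and all 4 experienced PBS libraries (−0.20 to 0.29) scored below all 4 naive ones (0.34 to 0.76). The list's most abundant members went both ways, with Bst2 at 28.5 and 19.4 CPM in naive and experienced PBS. Ccr2 was at 17.0 and 19.2, Cd68 at 14.9 and 15.3 and Slc40a1 at 5.73 and 17.3. This explanation thus stays open, as does an untested effect of past leukaemia.

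In the other fits, the real split called 3293 genes for LPS in naive mice and 1940 in experienced mice, and the highest other splits 1 and 3. In each, 1 of 35 splits, the real one, gave as many. That is the smallest share 35 splits can give, so chance is unlikely as the source of these counts but not excluded. Between experienced and naive PBS the real split called 0 and the highest other 1 (35 of 35 splits with at least as many). For the interaction these were 0 and 1 and for the averaged contrast 0 and 9 (100 of 100 drawn splits in each). Every split reaches a count of 0 by construction, so these 3 decide nothing about chance. Without the 4 least typical libraries, experienced against naive LPS gave 223 genes (0 where experienced PBS replicates 3 and 4 were kept) and the highest other split 2, but with 1 of 10 splits the share cannot go under 0.1. With the mitochondrial share as a covariate the real split called 0 genes and the highest other 1 (35 of 35, again by construction), and the covariate removes most of the exchanged split, since that share follows it.

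The tests of the difference between the LPS responses passed by camera for interferon-induced (median −0.54), megakaryocyte (0.43), erythroid (−1.81) and basophil genes (−1.0), all 4 with adjusted p = 0.567 with an estimated correlation.

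Experienced LPS replicate 4 had 7.30% mitochondrial counts against 1.91% to 2.50% in the other 3. Its list scores stood apart for MHC class II (−1.0), the interleukin-6 response (−0.34), the nuclear factor κB response (−0.37), cytokine receptors (−0.42), genes of the sort (−0.56) and glycolysis (−0.37). In CPM it was above the other 3 for Mt1 (264), Procr (7.29), Hoxa5 (6.19), Zbp1 (38.1), Ly6e (1616), Kit (573), Mki67 (1190), Txnip (310) and Hk1 (740). It was below them for Nop56 (379), Fcer1a (12.5), Hspa5 (479), Csf3r (48.3), Nfkbia (60.9), Sdf2l1 (23.5), Cdkn1a (19.8), Ifnar1 (48.0), Ldha (352) and Gapdh (941). Naive PBS replicate 4 had 17626 detected genes against 19510 to 19730, scores of −1.24 for heat shock and 0.32 for MHC class II genes, and CPM of 3.95 for Mt1, 20.5 for Aqp1 and 1.80 for Klf1. Experienced PBS replicate 4 stood apart in the unfolded protein response score (−0.035) and in CPM of Lsp1 (94.5), Rrp12 (57.6), Cd34 (536) and Cmpk2 (45.5). Naive LPS replicate 1 stood apart in Il1rl1 (184), Lmo4 (188), Ly6e (2322) and Ifit1 (39.2), replicate 2 of that group in the score of genes of the sort (−0.44) and in Ifitm3 (317), Bpifc (3.36) and Igkc (32.8), replicate 3 in Procr (3.62), Eya1 (18.9) and Gapdh (1468) and replicate 4 in Hmox1 (30.1). Naive PBS replicate 3 stood apart in the megakaryocyte score (−0.33) and naive PBS replicate 2 in Tle2 (29.0 CPM). Experienced PBS replicates 1 and 3 did so in Kit (733) and Cntnap1 (2.07), experienced LPS replicate 2 in Gata1 (63.2) and experienced LPS replicate 3 in Jchain (0.566) and CT010467.1 (105).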

How the results depend on the processing

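The alternatives that leave out the 2 or 4 least typical libraries or naive LPS replicate 3 with experienced LPS replicate 4, and the mitochondrial share as a covariate, were chosen after the results were seen. Of the values of the genes described in the text, each in the contrasts it is described for, 5639 kept their direction and side of the threshold, 66 lost a call, 26 gained one and 7 changed direction. Of all 21 genes fixed by name, those not called changed direction under at least 1 alternative in 13 cases between experienced and naive PBS, 9 between experienced and naive LPS, 4 for LPS in naive mice, 0 in experienced mice, 9 for the interaction and 14 in the averaged contrast, and 0 called ones did. Of those of the lists described, 901 kept both, 86 lost a call and 2 changed direction, judged by camera and not by the sign of the mean. In the interaction, the mean of the basophil list also turned positive without the 4 least typical libraries. The cause of a change was not tested unless the alternative's own construction gives it, as fewer libraries do.

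For LPS in naive mice, genes higher numbered 458 at an adjusted p of 0.01, 2260 with limma voom with quality weights, 374 with limma on log2(TPM + 1) and 2759 without the 4 least typical libraries, and genes lower 896 at an adjusted p of 0.01. Leaving out 1 library gave 768 (without naive PBS replicate 2) to 2184 genes higher (without experienced LPS replicate 4). In experienced mice, genes higher numbered 200 at an adjusted p of 0.01, 3521 with voom, 178 on log2(TPM + 1), 1126 with DESeq2, 1995 without the 2 and 2518 without the 4 least typical libraries and 1562 without naive LPS replicate 3 and experienced LPS replicate 4. Genes lower numbered 537 at an adjusted p of 0.01, 700 when only the libraries compared were fitted, 4021 with voom, 2136 without the 2 and 2488 without the 4 least typical libraries. Leaving out 1 library gave 302 (without experienced PBS replicate 1) to 1456 genes higher and 712 (without experienced LPS replicate 3) to 1701 genes lower, both highest without experienced LPS replicate 4.

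Between experienced and naive PBS, DESeq2 called 2 genes higher, voom 2 lower and limma on log2(TPM + 1) 1 lower, and without the 4 least typical libraries 1 was higher. Between experienced and naive LPS, DESeq2 called 2 higher and voom 2 lower. Without the 2 least typical libraries 0 were higher and 0 lower, without the 4, which also leaves out 2 PBS libraries, 70 were higher and 153 lower, and without naive LPS replicate 3 and experienced LPS replicate 4 the numbers were 94 and 107. That pair was chosen because each resembled the other group, so leaving it out sharpens the contrast by construction. For the interaction DESeq2 called 1 gene higher, and 77 were higher and 106 lower without that pair. In the averaged contrast 1 was higher without that pair, 2 lower with voom and 1 lower without the 4 least typical libraries.

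Between experienced and naive PBS, Car1, Il1rl1 and Mpo changed direction with voom (−0.56, −0.31 and −0.24) and without the 4 least typical libraries (−0.95, −0.56 and −0.35). Mpo ranged from −0.024 without experienced PBS replicate 4 to 0.66 without experienced PBS replicate 2. The erythroid and basophil lists changed direction without the 4 least typical libraries (means −0.50 and −0.93), and the glycolysis score for LPS in naive mice did on log2(TPM + 1) (−0.094). With an estimated correlation 0 lists were called in each of the 6 contrasts, and fry called 0 in the 4 contrasts other than the LPS responses. Between experienced and naive LPS, leaving out 1 library gave 7 (without experienced LPS replicate 3) to 18 lists called by camera (without experienced LPS replicate 4).

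The correlation of the LPS responses was 0.75 over genes with a mean log2 CPM of at least 4, 0.59 without the 2 and 0.65 without the 4 least typical libraries and 0.52 without naive LPS replicate 3 and experienced LPS replicate 4. Leaving out 1 library gave 0.57 (without experienced LPS replicate 4) to 0.72 (without experienced PBS replicate 4). With split naive PBS libraries the correlation of the difference at rest with the LPS response was 0.32.

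Replicate numbers did not pair the libraries. Of 24 same-numbered pairs from different groups 4 had deviations that correlated above 0.1, 3 of them between experienced PBS and experienced LPS (0.175, 0.222 and 0.321 for replicates 1, 2 and 4, against −0.123 for replicate 3), and in 4 of 24 the own number correlated best. The replicate block gave 1236 genes higher and 1684 lower for LPS in naive mice, 540 and 1052 in experienced mice and 0 in the other 4 contrasts, and of the calls of named genes it ended those of CT010467.1 and Ptprc. Genes changed 2-fold lie near what 4 libraries a group resolve, and the interaction recovered 10% of simulated 2-fold changes. Smaller changes were mostly missed. Of simulated 1.5-fold changes, 2% were recovered between experienced and naive PBS, 8% between experienced and naive LPS and 4% in the interaction.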

Other observations

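Which of the fixed lists to describe here was chosen after their values were seen, and no further test was added. After LPS, some cytokine receptor genes changed in level. In naive mice 4 of 22 receptor genes rose and 9 fell (4 and 15 adjusted over the list alone), and in experienced mice 2 rose and 5 fell (2 and 6 adjusted over the list alone). Csf2rb and Csf2rb2, near-identical signalling subunits of the interleukin-3 family receptors whose reads can be shared, rose in both, Csf2rb by 2.16 (SE 0.20) in naive and 2.11 (SE 0.20) in experienced mice. Flt3 fell in both, Il6ra, the interleukin-6 receptor, fell in naive mice (−1.58, SE 0.28) and Ifnar1, a chain of the type I interferon receptor, in experienced mice (−0.61, SE 0.13). As a list the receptors did not pass by camera in naive (median −0.54, adjusted p = 0.0536) or experienced mice (median −0.26, adjusted p = 0.38). Genes of the sort itself moved apart. Of 12 such genes, 2 rose and 3 fell in naive mice (2 and 7 adjusted over the list alone), and 2 rose and 4 fell in experienced mice (3 and 6 adjusted over the list alone). Besides the rise of Ly6a, Cd34, a surface protein of progenitors, fell in naive (−1.18, SE 0.17) and experienced mice (−0.90, SE 0.17), as did Itgam, a myeloid integrin among the lineage markers (−1.48, SE 0.24, and −1.97, SE 0.24). The list did not pass by camera (adjusted p = 0.0811 in naive and 0.185 in experienced mice).

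Targets of the tumour suppressor p53 went both ways in naive and in experienced mice. In naive mice 6 of 18 rose and 3 fell (8 and 3 adjusted over the list alone), with Pmaip1, a trigger of apoptosis, at 2.19 (SE 0.37), Zmat3 at 1.55 (SE 0.29) and the nuclease Aen at 0.84 (SE 0.13), against Sesn1, a stress-induced metabolic regulator, at −1.21 (SE 0.16). In experienced mice 3 rose and 2 fell (7 and 2 adjusted over the list alone), with Pmaip1 at 1.79 (SE 0.36), Aen at 0.71 (SE 0.13), Sesn1 at −1.01 (SE 0.15) and Trp53inp1 at −1.66 (SE 0.26). Cdkn1a, also a target, was the third to rise there (0.99, SE 0.27), and its difference between the 2 responses (0.96, SE 0.37) did not pass (edgeR adjusted p = 0.884). Camera gave adjusted p = 0.0811 in naive and 0.149 in experienced mice. Of 22 glycolysis and hypoxia genes, 2 rose and 2 fell in naive mice (2 and 2 adjusted over the list alone; camera, adjusted p = 0.658). In experienced mice 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.37 (camera, adjusted p = 0.000796, and adjusted p = 0.409 with an estimated correlation). Pfkp, an isoform of phosphofructokinase, rose in both (0.59, SE 0.15, and 0.87, SE 0.15). The lactate dehydrogenase gene Ldha (1.18, SE 0.24) and Gapdh (0.74, SE 0.18) rose in experienced mice. In naive mice Hk1, a hexokinase, rose (0.91, SE 0.23) and the glucose transporter gene Slc2a3 fell (−0.69, SE 0.15), and Pdk1, a kinase that limits entry of pyruvate into mitochondria, fell in naive (−0.81, SE 0.12) and experienced mice (−0.51, SE 0.12). With limma on log2(TPM + 1) the calls of Pdk1 and Pfkp in both kinds of mice, of Hk1 in naive mice and of Ifnar1, Ldha and Gapdh in experienced mice ended, and fry did not call the glycolysis list in experienced mice (adjusted p = 0.0519).

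Every one of the 16 libraries held both Xist, at 660 to 7387 CPM, and transcripts of the Y chromosome, with Ddx3y at 13.5 to 66.2 CPM and Kdm5d at 5.89 to 58.8 CPM. The labels do not give the sex of donors or recipients, so these data do not show whether donors of both sexes were pooled or cells of the recipients were sorted along with those of the donors.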
